A study of Mus musculus with 11 samples.

How the data were processed

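RNA came from luminal and basal cells sorted by CD24 and CD29 from mouse mammary outgrowths that carried a control hairpin (shLUC) or a hairpin against Ror2 (shROR2). Per the labels, the RNA was isolated with a PicoPure kit, amplified from biological triplicates with the NuGEN Ovation Pico kit, labelled with Cy3 and hybridized to one-colour Agilent mouse arrays. Used here were 11 arrays in 4 groups: luminal shLUC (3), luminal shROR2 (2), basal shLUC (3) and basal shROR2 (3). One more luminal shROR2 sample is not analysed here, so that group has 2 arrays. Groups were taken from the sample labels. The labels do not say which samples came from the same outgrowth, and no pairing was used.

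The scanner files hold intensity values that, per the file headers, Agilent Feature Extraction 11.0.1.1 background-subtracted and detrended within each array, with no normalization between arrays. The raw median signals of the same deposited files are intensities without correction. The authors' table holds intensity values on a linear scale with nearly the same median in every column, as quantile normalization between arrays would leave. How the authors normalized them and with which tool is not given in the sources used here. Its column medians were 89, 88.875 and 88.833 in luminal shLUC, 89 and 89.25 in luminal shROR2, 88.792, 88.833 and 89.333 in basal shLUC, and 89.083, 89.042 and 88.792 in basal shROR2. Its lowest value was 52.5, and its log2 values correlated at 0.996 to 0.998 with the raw median signal of the same array. These values are not centred and are not ratios, so no direction is at issue, but whether a background was subtracted before a normalization stays unknown.

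Each array holds 62976 spots, 59305 of them not controls, for 55681 different probes, and spots of the same probe were averaged. Between 52.8% and 59.5% of probes lay well above background per array. The 75th percentile of the processed signal ranged from 114.1 to 132.9, its median from 18.7 to 23.9, and the lowest signal well above background from 10.8 to 14.2. The scanner marked 110 to 163 outlier spots per array and 0 saturated ones, and no pair of arrays was identical. Probes were named through their RefSeq accessions with a gene table of mouse assembly GRCm38.p6, used for names only and not for coordinates. A symbol was found for 26582 probes and none for 29099, which were tested under their probe names.

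The values tested were log2 processed signal minus the 75th percentile of the array. Probes had to lie well above background on at least 3 of the 11 arrays, which 33630 did, 18260 of them with a symbol, and 18 with a missing value were left out. For genes with several probes (3490 genes) the probe with the highest mean was taken, and disagreement among probes is named. This left 29430 features, 14069 named genes and 15361 unnamed probes. A model with 4 group means was fitted to all arrays with limma 3.58.1 (lmFit and eBayes, prior degrees of freedom 1.85) in R 4.3.3 with the data.table package (1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Comparisons were shROR2 against shLUC in each compartment, their difference and their average, and basal against luminal cells within each hairpin. The p values were 2-sided, adjusted by Benjamini and Hochberg's method within a comparison, and called under 0.05. Ror2 did not pass the filter, so its groups were compared by exact permutation of the arrays.

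Genes named in the text were picked by a rule fixed before the data were examined: among called genes whose arrays do not overlap between the groups, the 8 with the largest change in each direction. For the difference between the compartments and for the average, overlap was not a condition. Where fewer than 5 were called, the list was filled to 5 by smallest p. Added were up to 4 genes with the smallest p of each gene list and the genes Wnt5a, Wnt4, Krt14, Krt5, Krt8, Krt18, Acta2, Axin2, Rock1, Rock2, Actn1 and Shroom2. Tested as sets were 24 gene lists, written from general knowledge, with limma's camera (inter-gene correlation 0.01, and estimated as an alternative), adjusted over the lists. Reported here are 23 of them, with the remaining list kept in the adjustment, and 2 genes the rule picked are left out of the text as well. The 23 lists cover myoepithelial, general luminal, hormone-sensing, and progenitor or alveolar markers, Wnt/β-catenin targets, Wnt ligands, receptors and polarity genes, SRF targets, basement membrane and integrins, cell junctions, Notch, branching growth factors, mesenchymal transition, cell cycle, interferon, immediate early and heat shock genes, hypoxia, p53, lipid synthesis, and fibroblast, endothelial, leukocyte, adipocyte and erythroid or muscle transcripts. The direction of a list is that of camera, and its shift is the median log2 change of its measured genes.

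On simulated data, with 50 genes changed per size among 29430, the luminal comparison recovered 0%, 8%, 70% and 90% of genes changed by a log2 of 0.5, 1, 2 and 3, the basal comparison 0%, 22%, 78% and 92%, and the average 6%, 50%, 90% and 100%. Of the calls made there, 4.55%, 1.03% and 4.65% were unchanged genes. The simulated noise had the same spread in every group for a given gene. The wider spread of the real basal shROR2 arrays was not modelled, so these shares may not hold for the data. The luminal and basal effects were correlated across genes and set beside 100 simulations without an effect, since genes are not independent samples.

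Alternatives tried were quantile normalization, normexp (offset 50) with quantile normalization, scaling by the array median, the authors' values, no filter, well above background on all arrays, a floor at the lowest signal well above background, the mean of a gene's probes, every probe by itself, the slide as a block, replicate blocks, a random block for samples with the same hairpin and number, array weights, a trended and robust prior, only the groups compared, a fold threshold of 1.5, and each array left out in turn. Normexp was run on raw median signals, since mean signals are not in the files used here. The slides (2) were fitted as a batch, as an alternative, in every comparison.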

Results

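The data came from mouse mammary outgrowths grown from transduced epithelial cells that carried a hairpin against Ror2 (shROR2) or a control hairpin against luciferase (shLUC). Ror2 is a receptor of non-canonical Wnt signalling, and the comparisons asked what the hairpin changed in each of the epithelial layers. Sorted luminal cells gave 3 shLUC and 2 shROR2 arrays, and sorted basal cells gave 3 shLUC and 3 shROR2 arrays. One more luminal shROR2 sample is not analysed here, so the luminal comparison rests on 2 against 3. Between 52.8% and 59.5% of probes lay well above background on every array, and no spot was saturated. The arrays lay on 2 slides, each holding 1 or 2 arrays of every group. Values given for a single slide thus rest on 1 or 2 arrays per group and only describe them. The fit with the slide as a block allows for a difference between the slides. Arrays of the same group correlated at 0.981 to 0.983 in luminal shLUC, 0.983 in luminal shROR2, 0.976 to 0.982 in basal shLUC, and only 0.941 to 0.953 in basal shROR2. The median standard deviation of bright probes was 0.229 in basal shROR2 against 0.117 in basal shLUC. The fit shared 1 spread per gene among all groups. Standard errors and adjusted p may thus be too small where basal shROR2 is compared, and too large in the luminal comparison. The first principal component carried 57.8% of the variance, and basal and luminal arrays correlated at 0.889 to 0.916. With 2 or 3 arrays per group, the number of arrays limited the precision of every comparison below. Changes are given as log2 change ± standard error, and adjusted p is from limma over 29430 tested features unless a list is named.

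Ror2, the gene that the hairpin targets, was measured by 1 probe that lay near background. Its processed signals were 3.14, 3.44 and 3.48 in luminal shLUC and 3.54 and 8.47 in luminal shROR2. In basal shLUC they were 11.1, 12.1 and 10.1, and in basal shROR2 16.8, 3.03 and 6.93. The only array with Ror2 well above background, and the highest of all 11, was the array labelled basal shROR2 replicate 1. On the scaled log2 scale, luminal shROR2 (mean -4.45, SD 0.94, n = 2) stood 0.67 above luminal shLUC (mean -5.12, SD 0.05, n = 3), with an exact permutation p = 0.3 over 10 regroupings. Basal shROR2 (mean -4.03, SD 1.24, n = 3) stood at -0.57 against basal shLUC (mean -3.46, SD 0.07, n = 3), with an exact permutation p = 0.7 over 20 regroupings. The smallest p these regroupings can give is 0.1. In the authors' table the differences were 0.03 (exact permutation p = 0.8) and -0.09 (exact permutation p = 0.7). Of the basal shROR2 arrays 2 lay below all basal shLUC arrays, and without each array in turn the basal difference ranged from -1.19 to 0.0489 and the luminal one from 0.0021 to 1.3357, each end of the latter resting on 1 luminal shROR2 array. With so few arrays and a signal this close to background, whether Ror2 transcript was lost could not be told in either compartment.

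Basal and luminal cells of the control outgrowths were compared to ask whether the sorted populations carried the identities their labels give. Acta2 (8.21 ± 0.13, adjusted p = 3.79e-09), Krt5 (7.87 ± 0.14, 4.34e-09), Cnn1 (7.70 ± 0.14, 5.05e-09) and Mylk (7.90 ± 0.30, 2.28e-07), genes of the contractile myoepithelial layer, were higher in basal cells (n = 3 and 3). Krt14 was higher by 5.34 ± 0.13 (adjusted p = 2.1e-08), and the chemokine gene Cxcl14 by 7.98 ± 0.20 (3.13e-08). Genes too dim in luminal cells to give a ratio were at least 251-fold (Cdh3), 189-fold (Snai2) and 79.1-fold (Moxd1) higher in basal cells. These bounds set the mean of the brighter group against the lowest signal well above background on the arrays of the dim group, or the probe's own signal where that was higher, a rule used for every "at least" below. Luminal keratins were lower in basal cells, Krt8 by -2.40 ± 0.13 (adjusted p = 1.92e-06) and Krt18 by -2.87 ± 0.12 (5.31e-07). So were Dmbt1 (-5.99 ± 0.68, 0.000231), Cldn6 (0.00227, well above background on 1 of 3 basal arrays), Clca1 (-5.63 ± 0.76, 0.000647) and the casein gene Csn1s2a (-5.42 ± 0.67, 0.000393). Luminal genes dim in basal cells were at least 25.4-fold (Timd2), 24.9-fold (Cyp3a57), 21.1-fold (Calca) and 12.7-fold (Ctsj) lower there. Among Wnt and cytoskeletal genes, Wnt4 was lower in basal cells (-1.12 ± 0.21, adjusted p = 0.0046), as was Shroom2 (-1.94 ± 0.35, 0.00349), and Actn1 was higher (2.42 ± 0.14, 2.43e-06). Wnt5a stood at -0.01 ± 0.12 (0.968), Rock1 at 0.26 ± 0.12 (0.146), Rock2 at 0.11 ± 0.13 (0.57), and Axin2, dim in luminal shLUC, had an adjusted p of 0.0593.

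Of the myoepithelial markers in the list, 19 of 20 were higher in basal cells over all genes and 19 adjusted over the list alone (median 5.73, camera adjusted p = 7.06e-29), with Id4 at least 33.6-fold higher. Among targets of serum response factor (SRF) 16 of 18 were higher, 17 adjusted over the list alone (median 3.05, 2.66e-20), with Myl9 at 7.40 ± 0.13. Basement membrane and integrin genes followed with 30 of 34 (30 adjusted over the list alone; median 2.42, 2.38e-22), among them Col7a1 (4.76 ± 0.10) and Col4a2 (5.37 ± 0.14). General luminal markers were lower for 17 of 19 genes, 18 adjusted over the list alone (median -2.27, 1.6e-14), with Krt19 at -3.95 ± 0.12. Hormone-sensing markers (14 of 17, 15 adjusted over the list alone; median -3.12, 2.18e-11; Cited1 -4.41 ± 0.18) and progenitor or alveolar markers (17 of 20, 17 adjusted over the list alone; median -2.98, 1.31e-11; Csn1s1 -4.62 ± 0.25) were lower as well. Wnt/β-catenin targets (median 0.95, 1.54e-06) and Wnt ligands, receptors and polarity genes (median 0.48, 0.000375) were higher in basal cells, with Lgr5 at least 15.5-fold and Wif1 at least 38.6-fold. Branching growth factors (0.91, 8.1e-07), mesenchymal transition genes (1.96, 1.01e-06) and hypoxia genes (0.55, 2.44e-05) were higher, and cell cycle genes lower (-0.68, 0.000174). The Notch ligands Jag1 (4.65 ± 0.16), Dll1 (at least 25.1-fold) and Jag2 (at least 12.1-fold) were higher in basal cells, though the Notch list as a whole did not pass (0.18, 0.163). Markers of other cells also differed between the gates: fibroblast (3.78, 1.99e-15) and endothelial (2.15, 8.78e-08) transcripts were higher in the basal gate, and leukocyte transcripts lower (-1.02, 4.69e-05; H2-Eb1 -1.54 ± 0.15). Cell junction (-0.52, 0.0507), immediate early and heat shock (-0.19, 0.71), interferon (-0.10, 0.564), p53 (-0.21, 0.744), lipid synthesis (-0.32, 0.0507), adipocyte (0.46, 0.25) and erythroid or muscle (-0.48, 0.726) lists did not pass. The lists that passed here all held with an estimated inter-gene correlation.

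In total 7939 features differed between basal and luminal shLUC cells (4033 higher, 3906 lower in basal), of which 4780 were named genes, and 6591 changed by at least 1.5-fold. For 1079 of them one group was dim. The balance turned under other settings, such as quantile normalization (3877 higher, 4497 lower). With the slide as a block 7432 features passed. List medians were, for example, 5.85, 5.62 and 5.80 for myoepithelial and -2.41, -2.33 and -2.28 for general luminal markers on slide 1, on slide 2 and with the slide as a block. The same comparison in shROR2 cells asked whether the layers stayed apart under the hairpin. It gave 6722 features (3113 higher, 3609 lower), and the balance turned with median scaling (3285 higher, 3151 lower), with only the groups compared in the fit (1604 and 1224), and without luminal shROR2 replicate 1 (2058 and 1718 of 3776) or replicate 2 (2066 and 1902 of 3968).

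Luminal shROR2 and shLUC cells were compared to ask what the hairpin changed in the layer that lines the duct. Serpina3f, a serine protease inhibitor gene, rose by 1.68 ± 0.14 (adjusted p = 0.0335; n = 2 and 3), and it was the only feature that passed. Its second probe moved the same way. Next in rank, but not passing, were Fstl1 (1.39 ± 0.14) and the contractile gene Myl9 (1.28 ± 0.14), each with an adjusted p of 0.0533, and Xlr3b (1.56 ± 0.20, 0.11). Snai2, which encodes a transcription factor of the basal layer, was at least 1.32-fold higher (adjusted p = 0.0533) and was well above background on 0 of 3 luminal shLUC arrays. The lowest p values in the other direction included those of Gja1 (-0.59 ± 0.11, 0.288), Smc3 (-0.78 ± 0.16, 0.324), Cbln4 (at least 2.07-fold lower, 0.211) and Slc14a1 (dim in both groups, 0.143). Among genes fixed in advance, Acta2 stood at 0.88 ± 0.14 (0.162), Krt5 at 0.07 ± 0.15, Krt14 at -0.10 ± 0.14, Krt8 at -0.01 ± 0.14, Krt18 at 0.16 ± 0.14, Wnt5a at -0.25 ± 0.14 and Wnt4 at -0.01 ± 0.24. Rock1 (-0.18 ± 0.13), Rock2 (-0.05 ± 0.14), Actn1 (0.10 ± 0.15) and Shroom2 (-0.02 ± 0.39) did not pass either, and Axin2 was dim in both groups.

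The gene lists showed a clearer shift than single genes. Myoepithelial markers lay higher in luminal shROR2 cells (median 0.17, quartiles 0.03 to 0.54, camera adjusted p = 3.61e-07; 0.22, 0.20 and 0.18 on slide 1, on slide 2 and with the slide as a block). Of its genes 0 passed over all genes and 6 adjusted over the list alone, with Acta2 as above, Sparc at 0.61 ± 0.13 and Vim at 0.51 ± 0.11. Mesenchymal transition genes (0.18, 4.3e-05, with 0.40, 0.08 and 0.18 by slide and block) had 0 and, adjusted over the list alone, 3, with Fn1 at 0.94 ± 0.14. Fibroblast transcripts (0.61, 3.91e-09; 0.34, 0.60 and 0.58) had 0 and, adjusted over the list alone, 8, among them Dcn (0.89 ± 0.14), Thy1 (1.18 ± 0.34) and Col1a2 (0.61 ± 0.17). Leukocyte transcripts (0.63, 1.73e-09; 0.63, 0.56 and 0.58) had 0 and, adjusted over the list alone, 7, with Lyz1 at 0.78 ± 0.15, H2-Ab1 at 0.58 ± 0.15 and Cd74 at 0.56 ± 0.15. These 4 lists held with an estimated inter-gene correlation (adjusted p = 0.0239, 0.0329, 0.0111 and 0.0111).

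Other luminal lists passed only with the preset correlation. Basement membrane and integrin genes lay higher (0.20, camera adjusted p = 4.3e-05, adjusted p = 0.0604 with an estimated correlation, with 0.23, 0.13 and 0.21 by slide and block), with 3 genes adjusted over the list alone and Col4a2 at 0.65 ± 0.16. So did immediate early and heat shock genes (0.16, 2.05e-06, 0.0604 with an estimated correlation; 0.24, 0.15 and 0.18), with 1 gene adjusted over the list alone, Btg2 at 0.89 ± 0.13. Endothelial transcripts (0.81, 2.05e-06, 0.0535 with an estimated correlation; 0.63, 0.84 and 0.75) had 2 genes adjusted over the list alone, with Plvap at 1.09 ± 0.26. Adipocyte transcripts (0.36, 0.0135, 0.0693 with an estimated correlation; 0.43, 0.32 and 0.40) had 1, Fabp4 at 0.98 ± 0.16. Hormone-sensing (0.19, 0.0103; 0.0604; 0.23, 0.20 and 0.20), hypoxia (0.18, 0.0013; 0.0812; 0.24, 0.05 and 0.17) and erythroid or muscle lists (0.45, 0.00264; 0.139; 0.49, 0.64 and 0.48) lay higher with 0 genes adjusted over the list alone, the adjusted p with an estimated correlation second. Cell cycle genes lay lower (-0.20, 0.00576, 0.0704 with an estimated correlation; -0.07, -0.19 and -0.21), with Rrm2 at -0.98 ± 0.25. Of these, 4 lost their call without 1 array: cell cycle without luminal shLUC replicate 2 (0.0791), hypoxia (0.0914) and hormone-sensing (0.0539) without luminal shROR2 replicate 1, and erythroid or muscle without luminal shROR2 replicate 2 (0.0506). For all 12 lists the direction was kept without each of the 11 arrays in turn. Not passing were the Wnt/β-catenin targets (-0.01, 0.899), Wnt ligands, receptors and polarity genes (-0.05, 0.546), SRF targets (0.09, 0.0507), cell junction (-0.04, 0.899), Notch (0.14, 0.0633), branching (-0.01, 0.489), interferon (-0.13, 0.514), p53 (0.10, 0.0753), lipid synthesis (0.05, 0.296), general luminal (0.01, 0.536) and progenitor or alveolar lists (0.10, 0.271).

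Beside the single luminal call, 1632 features had an unadjusted p under 0.05, where 1472 would be called by chance. Serpina3f had an adjusted p of 0.0704 with the slide as a block, and 0 features passed then. Without 1 array, the luminal count was 6 (luminal shROR2 replicate 1), 10 (basal shROR2 replicate 2), 1 (the array labelled basal shROR2 replicate 1) or 0 (each of the other 8). Serpina3f lost its call without 9 of the 11 arrays, with adjusted p between 0.0502 (basal shROR2 replicate 3) and 0.201 (luminal shROR2 replicate 2). On simulated data with an equal spread in all groups, this comparison recovered 8% of genes changed by a log2 of 1 and 70% of those changed by 2. Under that setting changes of 2-fold were mostly missed.

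Basal shROR2 and shLUC cells were compared to ask what the hairpin changed in the contractile, stem cell-bearing layer. Immediate early and heat shock genes rose, Hspa1a by 1.61 ± 0.14 (adjusted p = 0.00491), Btg2 by 1.08 ± 0.12 (0.0112), Atf3 by 1.03 ± 0.10 (0.00739) and Fosb by 0.86 ± 0.09 (0.00982; n = 3 and 3). The Notch target and feedback gene Nrarp rose by 1.92 ± 0.25 (0.0185) as the Notch ligand gene Jag1 fell by 0.94 ± 0.16 (0.0384). Fhl2, a target of SRF, fell by 0.66 ± 0.11 (0.039), and the desmosome gene Pkp1 fell by 0.69 ± 0.13 (0.047). Clca1 rose by 5.05 ± 0.76 (0.0275), the milk gene Lalba by 1.40 ± 0.25 (0.0465) and Stc2 by 1.03 ± 0.19 (0.0493). All of these are higher in luminal cells, but of the general luminal list 0 genes passed, with 11 higher and 8 lower, and the list did not hold with an estimated correlation (0.197). The array labelled basal shROR2 replicate 1 had the highest Ror2 signal, from a probe near background, and without it 904 features passed, 34.3% of them higher in shROR2. The count also rose without replicate 2 (446, 37% higher) or replicate 3 (454, 35% higher) of that group, so a rise was not particular to this array.

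Tnf rose (0.0439) from a signal well above background on 1 of 3 basal shLUC arrays, and genes dim in basal shLUC were higher by at least 3.74-fold (Ctsr, 0.019), 2.39-fold (Mmrn1, 0.00234), 1.66-fold (Cers3, 0.037), 1.30-fold (Orc1, 0.0112) and 1.15-fold (Zfp979, 0.0247). Of these, Cers3 and Zfp979 were well above background on only 1 of 3 basal shROR2 arrays, and Orc1 on 2. Genes dim in basal shROR2 were lower by at least 2.68-fold (Cdk15, 0.0264), 2.16-fold (Proca1, 0.037), 2.11-fold (Lig4, 0.0467), 2.08-fold (Nkain3, 0.00364), 1.75-fold (Zfp65, 0.00811), 1.74-fold (Bloc1s5, 0.0281), 1.73-fold (Optc, 0.00217) and 1.21-fold (Depdc1b, 0.037). Of genes fixed in advance none passed: Wnt5a stood at -0.29 ± 0.12 (0.299), Wnt4 at -0.19 ± 0.21 (0.719), Rock1 at -0.51 ± 0.12 (0.0874), Rock2 at -0.16 ± 0.13 (0.59), Actn1 at -0.34 ± 0.14 (0.271) and Shroom2 at 0.77 ± 0.35 (0.333), and Axin2, well above background on 1 of 3 basal shLUC arrays, had an adjusted p of 0.245. Krt5 (-0.32 ± 0.14, 0.303), Krt14 (-0.08 ± 0.13, 0.818), Acta2 (-0.14 ± 0.13, 0.645), Krt8 (-0.11 ± 0.13, 0.714) and Krt18 (0.46 ± 0.12, 0.129) did not pass either.

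Immediate early and heat shock genes moved as a group in basal cells (median 0.46, quartiles 0.19 to 0.64, camera adjusted p = 1.28e-15; 0.34, 0.53 and 0.46 on slide 1, on slide 2 and with the slide as a block), with 6 of 24 passing over all genes and 12 adjusted over the list alone. Leukocyte transcripts rose beside them (1.06, 2e-13, with 0.93, 0.88 and 1.06 by slide and block), with 7 of 19 and, adjusted over the list alone, 10: Cd74 by 1.27 ± 0.13 (0.00926), Lyz1 by 1.16 ± 0.14 (0.0118), H2-Ab1 by 1.12 ± 0.13 (0.0118) and Tyrobp by 1.51 ± 0.18 (0.0131). Endothelial transcripts rose too (0.93, 5.07e-09; 0.90, 1.32 and 0.93), with all 15 positive, 2 passing and, adjusted over the list alone, 7, where Plvap rose by 1.35 ± 0.23 (0.0425) and Emcn by 1.5 ± 0.28 (0.0483). Hormone-sensing genes lay higher as a list (0.34, 0.00261; 0.20, 0.48 and 0.34), with Stc2 passing and 4 adjusted over the list alone, and Prlr at 1.31 ± 0.25 (0.0577). These 4 lists held with an estimated inter-gene correlation (adjusted p = 0.0188, 0.00723, 0.0331 and 0.0367).

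Another 7 basal lists passed only with the preset correlation. SRF targets lay lower (-0.24, camera adjusted p = 0.000387, adjusted p = 0.0592 with an estimated correlation, with -0.28, -0.11 and -0.24 by slide and block), with Fhl2 passing, 4 adjusted over the list alone and Thbs1 at -0.51 ± 0.11 (0.0774). Basement membrane and integrin genes lay lower (-0.22, 0.00745, 0.169 with an estimated correlation; -0.29, -0.05 and -0.22), with 0 passing and, adjusted over the list alone, 1 higher and 1 lower. Myoepithelial markers lay lower (-0.16, 0.0299, 0.186 with an estimated correlation; -0.26, -0.07 and -0.16), with 0 on either count and Id4 at -0.42 ± 0.10 (0.106). General luminal (0.24, 0.0295, 0.197 with an estimated correlation; 0.04, 0.26 and 0.24), progenitor or alveolar (0.23, 0.0239; 0.269; 0.07, 0.19 and 0.23) and Notch lists (0.26, 0.0282; 0.0925; 0.17, 0.20 and 0.26) lay higher as lists. Adjusted over the list alone, 6, 2 and 2 of their genes were higher and 1 in each was lower, and over all genes 1 progenitor or alveolar gene and 1 Notch gene passed as higher, and Jag1 as lower. Adipocyte transcripts (0.08, 0.0453, 0.149 with an estimated correlation; 0.05, 0.02 and 0.08) included Fabp4, which rose by 1.02 ± 0.14 (0.0216), and 3 genes passed adjusted over the list alone. Leaving out 1 array ended 6 of these calls: myoepithelial (0.178) and basement membrane (0.0759) without the array labelled basal shROR2 replicate 1, general luminal (0.116) and adipocyte (0.116) without basal shROR2 replicate 2, progenitor or alveolar (0.0966) and Notch (0.0609) without basal shROR2 replicate 3. Directions of all these passing lists were kept without each of the 11 arrays. Not passing were the Wnt/β-catenin targets (-0.04, 0.711), Wnt ligands, receptors and polarity genes (-0.16, 0.305), cell junction (-0.01, 0.973), branching (-0.10, 0.766), mesenchymal transition (0.06, 0.168), cell cycle (0.13, 0.156), interferon (0.02, 0.0693), hypoxia (-0.09, 0.416), p53 (0.09, 0.282), lipid synthesis (-0.07, 0.973), fibroblast (0.25, 0.352) and erythroid or muscle lists (0.55, 0.0533).

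In total 284 features passed in basal cells, 113 higher and 171 lower in shROR2, of which 185 were named genes (89 higher, 96 lower), and 274 changed by at least 1.5-fold. For 53 one group was dim. The share higher was 39.8%, and 52.9% when arrays were scaled by their median, so the balance of directions depended on the scaling. With the slide as a block 133 features passed, and of 31 called genes picked for naming and followed under other settings 20 kept their call and 11 lost it. Every array left out moved the count: to 904, 446 and 454 without the array labelled basal shROR2 replicate 1 and replicates 2 and 3 of that group, 19, 29 and 74 without basal shLUC replicates 1, 2 and 3, 86, 95 and 96 without luminal shLUC replicates 1, 2 and 3, and 95 and 95 without luminal shROR2 replicates 1 and 2. With only the basal arrays in the fit 0 features passed in limma, with 3129 at an unadjusted p under 0.05. With array weights, which were lowest for the basal shROR2 arrays, 43 passed. The adjusted p of single basal genes thus rests on a spread shared with less variable groups. In simulated data 22% of genes changed by a log2 of 1 and 78% of those changed by 2 were recovered in this comparison. That simulation gave all groups an equal spread, which the basal shROR2 arrays did not have, so recovery in the real data is not known.

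**Figure D1:**
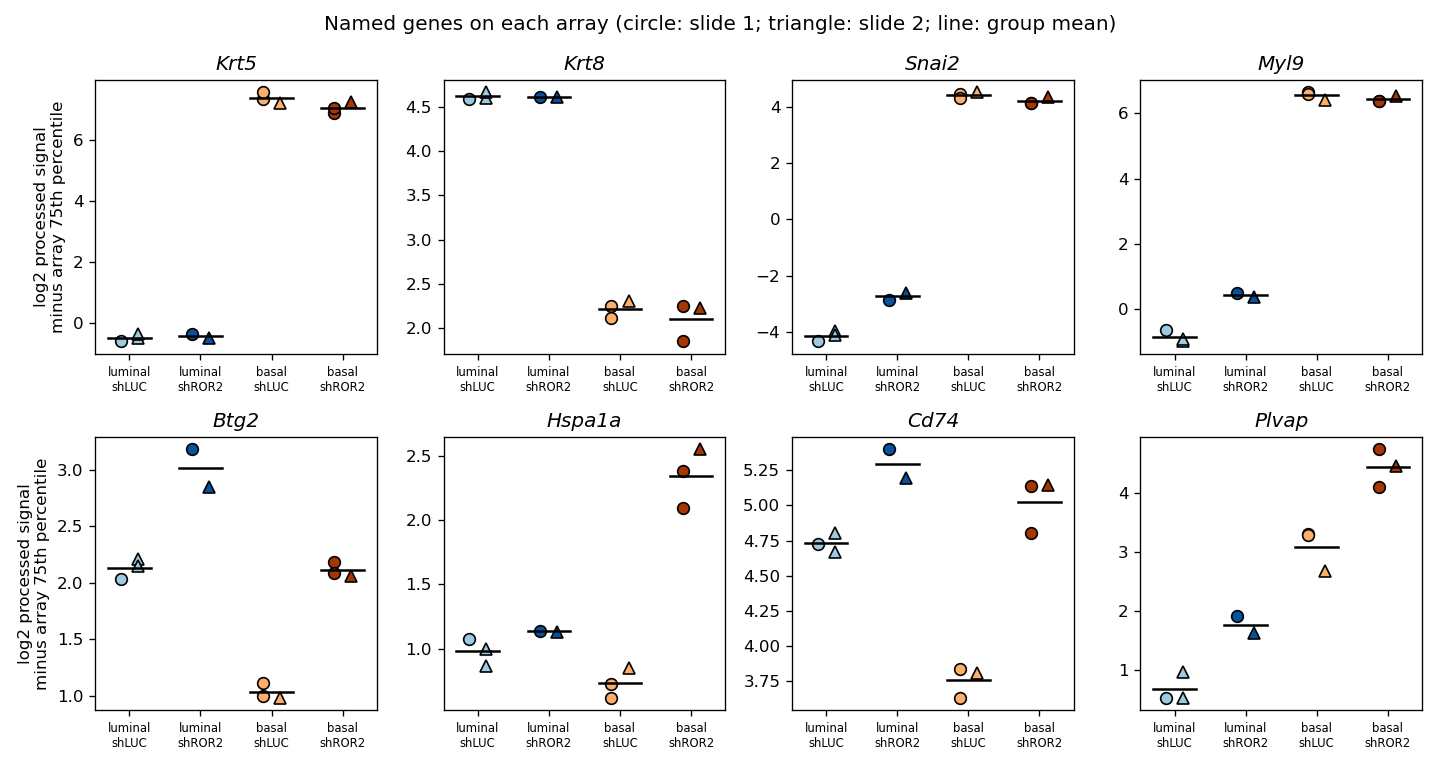
Level of 8 genes on each array, as log2 processed signal minus the array's 75th percentile; circles are slide 1, triangles slide 2 and lines group means (3 arrays, or 2 for luminal shROR2). Krt5 and Krt8 mark the layers, Snai2 and Myl9 stood higher in luminal shROR2 without passing, and Btg2, Hspa1a, Cd74 and Plvap rose in basal shROR2.

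The difference between the basal and luminal effects of the hairpin was tested to ask what was specific to a compartment. No single gene passed in limma: the nearest was Optc (adjusted p = 0.0594), dim in 3 of the 4 groups, followed by Mmrn1 (0.0665), Nkain3 (0.0891), Ecel1 (0.0891) and Orc1 (0.0925), each dim in at least 1 group. Among bright genes Fstl1 stood at -1.49 ± 0.19 (0.0891), Myl9 at -1.39 ± 0.19 (0.121), Acta2 at -1.02 ± 0.19 (0.238) and Hspa1a at 1.46 ± 0.21 (0.132). Snai2 (0.0891), Slc14a1 (0.132) and Ubd (1.84 ± 0.30, 0.194) did not pass. Of the genes fixed in advance, Wnt5a (-0.05 ± 0.19), Wnt4 (-0.18 ± 0.32), Krt5 (-0.39 ± 0.21), Krt14 (0.02 ± 0.19), Krt8 (-0.11 ± 0.19), Krt18 (0.30 ± 0.19), Rock1 (-0.33 ± 0.18), Rock2 (-0.11 ± 0.19), Actn1 (-0.44 ± 0.20), Shroom2 (0.79 ± 0.53) and Axin2 (dim in luminal cells, 0.708) did not pass. Beside the count of 0, 2440 features had an unadjusted p under 0.05 against 1472 by chance; quantile normalization gave 2, the authors' values 7, and the slide as a block 0. Leaving out basal shLUC replicate 3 gave 1 feature, the array labelled basal shROR2 replicate 1 gave 1, and basal shROR2 replicate 3 gave 7.

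Gene lists did separate the compartments, chiefly contractile and matrix genes, on which the hairpin's effect was lower in basal than in luminal cells. The basal minus luminal difference was -0.48 for myoepithelial markers (camera adjusted p = 1.44e-07; -0.54, -0.38 and -0.49 on slide 1, on slide 2 and with the slide as a block; 5 genes adjusted over the list alone). It was -0.41 for basement membrane and integrin genes (5.7e-07; -0.46, -0.33 and -0.42; 1 gene adjusted over the list alone), with Fn1 at -1.19 ± 0.19, and -0.30 for SRF targets (3.91e-06; -0.23, -0.30 and -0.29; 3 genes adjusted over the list alone). These 3 differences held with an estimated correlation (0.0341, 0.0434 and 0.0415). The changes within a compartment were less certain: with an estimated correlation the basal ones did not hold (0.186, 0.169 and 0.0592), and of the luminal ones only that of myoepithelial markers did (0.0239, against 0.0604 and 0.191). Of 20 myoepithelial markers 5 are also SRF targets and 2 are mesenchymal transition genes, so these lists are not independent. Immediate early and heat shock genes (0.24, 7.02e-07, adjusted p = 0.0594 with an estimated correlation, with 0.08, 0.33 and 0.24 by slide and block; 3 genes adjusted over the list alone), leukocyte transcripts (0.34, 0.000351, 0.0538 with an estimated correlation; 0.28, 0.28 and 0.25) and cell cycle genes (0.24, 0.0025, 0.0594 with an estimated correlation; 0.11, 0.27 and 0.22; 1 gene adjusted over the list alone) differed in the other direction. Fibroblast transcripts (-0.60, 0.00157, 0.0594 with an estimated correlation; -0.84, -0.40 and -0.61; 3 genes adjusted over the list alone) and hypoxia genes (-0.23, 0.00795, 0.161 with an estimated correlation; -0.45, 0.04 and -0.24) differed as the matrix genes did. The hypoxia call was lost without luminal shROR2 replicate 1 (0.101). The other lists did not pass, the nearest being interferon (0.08, 0.0692) and endothelial (0.25, 0.0749), and the Wnt/β-catenin targets stood at -0.04 (0.788).

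**Figure D2:**
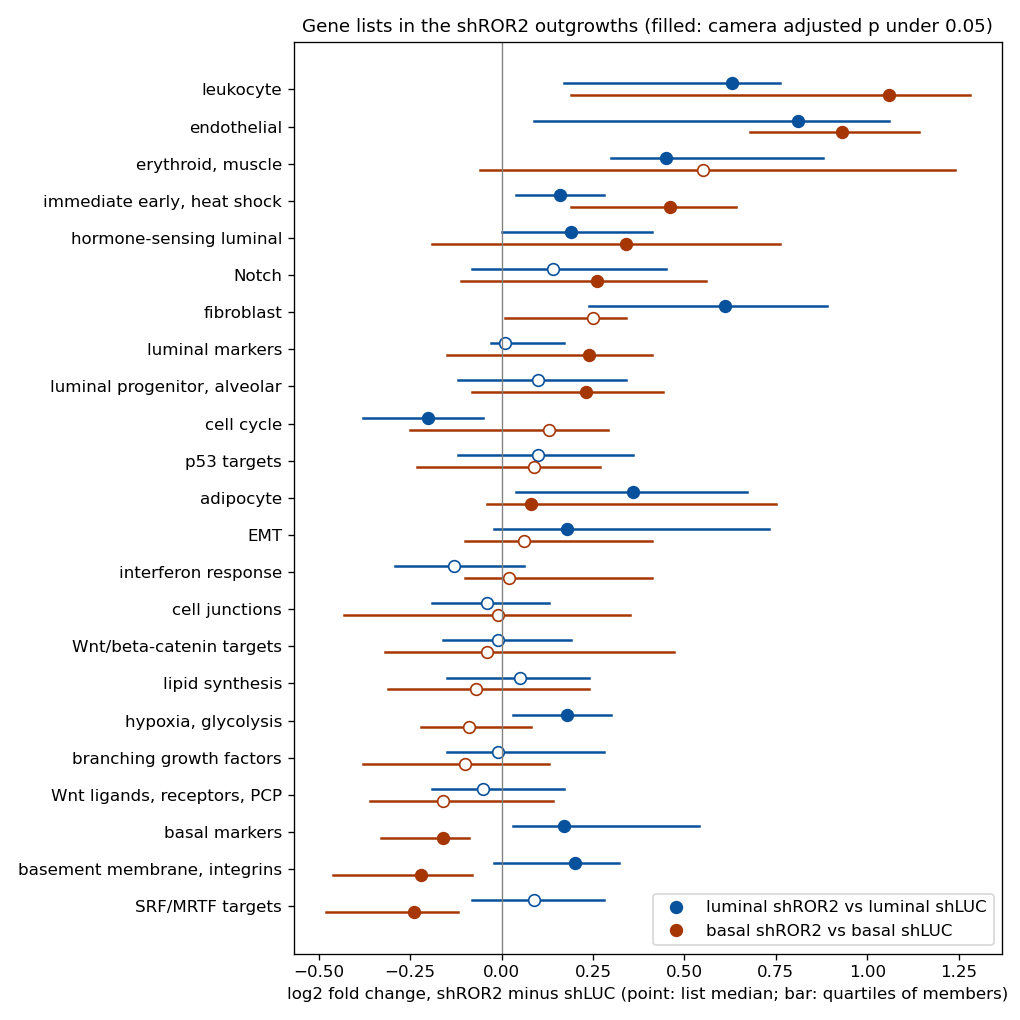
Median log2 change of each gene list under the Ror2 hairpin in luminal (blue) and basal (brown) cells, with bars spanning the quartiles of the members. Filled points mark lists with a camera adjusted p under 0.05, with the preset inter-gene correlation.

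The average of the luminal and basal effects was tested to ask what the hairpin changed over both layers, though a change in 1 layer can carry an average. Btg2 (0.98 ± 0.09, adjusted p = 0.0113), Atf3 (0.67 ± 0.07, 0.0132), Fosb (0.61 ± 0.07, 0.0154) and Hspa1a (0.88 ± 0.10, 0.0165) rose, the last chiefly in basal cells (luminal means 0.98 in shLUC and 1.13 in shROR2), as did Lyz1 (0.97 ± 0.10, 0.012), Cd74 (0.92 ± 0.10, 0.0128), the complement gene C1qc (1.35 ± 0.14, 0.012) and Plvap (1.22 ± 0.18, 0.0317). Lalba (1.5 ± 0.19, 0.0183), Nrarp (1.20 ± 0.19, 0.0408), Procr (0.91 ± 0.14, 0.0434) and Tgfb3 (0.52 ± 0.09, 0.0467) rose as well. Myl9 passed (0.58 ± 0.09, 0.0449) through its luminal rise alone, with basal means of 6.55 in shLUC and 6.44 in shROR2. Clca1 (3.50 ± 0.57, 0.0449), Rnase2a (2.08 ± 0.33, 0.0441), Xlr3b (1.43 ± 0.14, 0.0113) and Mustn1 (1.33 ± 0.17, 0.0177) rose, and Mmrn1 (0.012) and Ctsr (0.0382) rose from a dim signal in basal shLUC. Traip (-1.28 ± 0.17, 0.0228), Morrbid (-0.97 ± 0.13, 0.0277), Il4i1 (0.0454, well above background on 1 of 3 basal shROR2 arrays), Usp31 (-0.76 ± 0.13, 0.0497; 2 of 3 probes the same way), Arhgap12 (-0.69 ± 0.10, 0.0311) and Fhl2 (-0.55 ± 0.08, 0.0379) fell, as did Zfp65 (0.0166), Nkain3 (0.0172) and Optc (0.0113) to a dim signal. Mmrn1, Nkain3 and Optc were dim in luminal cells with either hairpin, so a luminal change in them could not be measured. Their difference between the compartments did not pass. Snai2 (0.0563), dim in luminal shLUC, did not pass, nor did Acta2 (0.37 ± 0.10, 0.162), Wnt5a (-0.27 ± 0.09, 0.297), Krt18 (0.31 ± 0.09, 0.228), Rock1 (-0.34 ± 0.09, 0.16), Axin2 (dim in luminal cells, 0.528) or Shroom2 (0.38 ± 0.26). Wnt4 (-0.10 ± 0.16), Krt14 (-0.09 ± 0.10), Krt5 (-0.13 ± 0.10), Krt8 (-0.06 ± 0.10), Rock2 (-0.10 ± 0.10) and Actn1 (-0.12 ± 0.10) did not either.

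Of gene groups, immediate early and heat shock genes (median 0.27, camera adjusted p = 2.65e-16, with 0.29, 0.30 and 0.26 by slide and block) rose with 5 of 24 genes passing and 12 adjusted over the list alone. Leukocyte transcripts (0.85, 3.85e-16; 0.82, 0.77 and 0.85) had 7 of 19 and, adjusted over the list alone, 11, and endothelial transcripts (0.92, 4.01e-11; 0.72, 1.22 and 0.96) had 1 of 15 and, adjusted over the list alone, 10. Hormone-sensing (0.30, 0.000279; 0.22, 0.32 and 0.32), mesenchymal transition (0.34, 0.000206; 0.33, 0.30 and 0.34) and fibroblast lists (0.44, 6.6e-05; 0.33, 0.50 and 0.42) had 0 genes passing. Adjusted over the list alone 6, 6 and 8 of their genes were higher, and 1, 0 and 1 lower. These 6 lists held with an estimated inter-gene correlation (0.0166, 0.00401, 0.0183, 0.0218, 0.031 and 0.0308). Adipocyte transcripts (0.29, 0.00977, adjusted p = 0.0551 with an estimated correlation; 0.43, 0.41 and 0.29; Fabp4 1.00 ± 0.10, 0.012), Notch genes (0.14, 0.0106, 0.0551 with an estimated correlation; 0.15, 0.13 and 0.14) and erythroid or muscle transcripts (0.60, 0.00199, 0.189 with an estimated correlation; 0.62, 0.58 and 0.61) lay higher as lists, and only with the preset correlation. So did progenitor or alveolar (0.15, 0.0169, 0.306 with an estimated correlation; 0.10, 0.18 and 0.16) and general luminal markers (0.13, 0.0339, 0.259 with an estimated correlation; 0.10, 0.15 and 0.15), which lost their calls without basal shROR2 replicate 3 (0.0517) and luminal shROR2 replicate 1 (0.0897). The other lists did not pass, among them myoepithelial (0.07, 0.121), basement membrane (-0.06, 0.788), Wnt/β-catenin targets (-0.02, 0.796), and Wnt ligands, receptors and polarity genes (-0.09, 0.334).

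In the average 135 features passed, 83 higher and 52 lower (the balance turned to 144 and 166 without the array labelled basal shROR2 replicate 1, 86 and 102 without replicate 3 of that group, and 16 and 17 without luminal shLUC replicate 3), of which 88 were named genes (67 higher, 21 lower), and 111 changed by at least 1.5-fold. With the slide as a block 60 passed, and of 27 called genes picked for naming and followed under other settings 19 kept their call and 8 lost it. Without 1 array the count was 0, 1 and 33 (luminal shLUC replicates 1, 2 and 3), 22 and 0 (luminal shROR2 replicates 1 and 2), 15, 32 and 67 (basal shLUC replicates 1, 2 and 3) or 310 (the array labelled basal shROR2 replicate 1), and 180 and 188 without the other 2 basal shROR2 arrays. Across all features the luminal and basal effects correlated weakly (Pearson r = 0.114, Spearman correlation 0.112), outside the -0.033 to 0.024 of 100 simulations without an effect, and 54.1% had the same sign (49.3% to 50.8% simulated). These simulations hold no other difference that luminal and basal cells of the same outgrowths could share, so they cannot tie the correlation to the hairpin. Of the 284 basal calls, 73.2% had the same sign in luminal cells (r = 0.488), with no simulated range for either value. Among the lists, leukocyte transcripts lay higher in both compartments with either correlation, and more so in basal cells with the preset one (0.000351). Immediate early and heat shock genes lay higher as a list in both with the preset correlation, but in luminal cells not with an estimated one (0.0604). In luminal cells 0 genes of either list passed over all genes.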

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

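Of the tests in this part, the one on noise of dim probes, both on basal cells, and both on the immediate early and heat shock genes were chosen only after the result was seen, and those on the second leukocyte and the perivascular lists before. What drew attention here was a difference between groups: the hairpin's effect on 8 of the reported gene lists differed between basal and luminal cells, by camera on the interaction term of the fit. The adjusted p was 1.44e-07 for myoepithelial markers, 5.7e-07 for basement membrane and integrin genes and 3.91e-06 for SRF targets, and these 3 held with an estimated inter-gene correlation. It was 7.02e-07 for immediate early and heat shock genes, 0.000351 for leukocyte transcripts, 0.00157 for fibroblast transcripts, 0.0025 for cell cycle genes and 0.00795 for hypoxia genes, and these 5 did not hold (0.0594, 0.0538, 0.0594, 0.0594 and 0.161).

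Leukocyte transcripts stood higher in shROR2 cells of both compartments, and more so in basal cells only with the preset correlation. If more leukocytes had come through the sort, leukocyte genes outside the list should move with it: a second list of 19 genes, 18 of them measured and none shared with the first, had a median average change of 0.45 (14 positive, lower quartile 0.20, camera p = 8.23e-07, or 0.0113 with an estimated correlation), as that source predicts. Noise of dim probes was excluded, since the 14 genes well above background on all arrays had a median of 0.79. Sorting on CD24 and CD29 does not by itself remove leukocytes, which a CD45 gate would, and Cd74 stood at 4.73 in luminal shLUC and 5.30 in luminal shROR2, and at 3.76 and 5.03 in basal cells (log2 over the 75th percentile). These arrays could not tell whether the outgrowths attracted more leukocytes, the sort let more through, or the epithelial cells made more of these transcripts.

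Contractile and matrix genes stood higher in luminal shROR2 cells. With an estimated correlation only the myoepithelial list held (0.0239), not basement membrane and integrin genes (0.0604), and SRF targets did not pass with either (0.0507 and 0.191). In luminal shLUC cells 14 of the 20 myoepithelial markers were well above background on all arrays. Basal cells in the luminal gate are 1 possible source: the 220 genes over 16-fold higher in basal than luminal shLUC cells had a median luminal change of 0.20 (159 positive, quartiles -0.05 to 0.68). This decided nothing, and the same luminal shLUC arrays served to pick these genes and to measure their change, which by itself favours a rise. A further test, made because that gave no decision, asked whether the share of basal RNA that 6 risen genes implied (0.772%, from genes picked because they had risen) also raised Krt5, Krt14, Krt17 and Cnn1: their median was -0.01 where 1.23 was predicted, and Krt5 stood at 0.07 ± 0.15 against 1.48. This argues against basal cells with these keratins, which a stricter CD29 gate would remove, as the sole source. It leaves open a smaller contribution or a gain of contractile genes by luminal cells themselves. The shares that the 6 genes implied were uneven, from 0.284% (Acta2) to 2.24% (Fstl1), and Tagln, not used in the test, implied 0.582%. Perivascular cells share contractile genes, and a gate against PDGFRB would remove them. They were not decided by 9 measured genes of 10 (median 0.40, 7 positive, camera p = 0.0179, or 0.0618 with an estimated correlation). Rgs5 rose by 1.04 ± 0.23, from -0.69 to 0.35, while Cspg4 stood at -0.43 ± 0.19 and Mcam at -0.14 ± 0.13. Fibroblast (0.61, 0.0111 with an estimated correlation) and endothelial transcripts (0.81, 0.0535) also stood higher in luminal shROR2 cells, so other stromal cells, not tested as a source, stay open as well.

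Immediate early and heat shock genes stood higher in basal shROR2 cells, with all 24 measured genes well above background on every array. No 1 array carried this: the list's median of 0.46 was 0.37 at the lowest when each basal shROR2 array was left out, and each array by itself had a median of 0.39 (the array labelled basal shROR2 replicate 1), 0.49 and 0.32. Stress of dissociation before the sort would act on luminal cells too if they were dissociated alongside, which the labels do not say, and their median was 0.16, a rise that did not hold with an estimated correlation (0.0604). Neither did the difference between compartments (7.02e-07, then 0.0594), so this did not decide it. A response of basal cells to the hairpin is 1 biological alternative, and samples fixed before dissociation could test it. Leukocyte (median 1.06) and endothelial transcripts (0.93) also stood higher in basal shROR2 cells, so such cells, not tested as a source, stay open.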

How the results depend on the processing

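No alternative in this part was chosen after the results were seen. For every count, list and gene below that moved, the cause was not tested unless it is given.

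The luminal count of 1 was 5 with quantile normalization, 22 with normexp, 0 with median scaling, 21 with the authors' values, 3 without a filter, 4 with probes well above background on all arrays, 5 with a floor, 0 with the mean of probes, 0 with the slide as a block, 62 with array weights, 25 with a trended and robust prior, and 0 with only the groups compared, where 2958 had an unadjusted p under 0.05 and fewer arrays estimate the variance. Leave-one-out gave 0 to 10. The basal count of 284 was 539 with normexp, 541 with the authors' values, 135 without a filter, 476 with probes well above background on all arrays, 441 with a floor, 133 with the slide as a block, 43 with array weights, 665 with a trended and robust prior, and 0 with only the groups compared (3129 unadjusted). Leave-one-out gave 19 to 904. The interaction count of 0 was 2 with quantile normalization, 7 with normexp, 1 with median scaling, 7 with the authors' values and 24 with a trended and robust prior, and 0 to 7 in leave-one-out. The average count of 135 was 298 with normexp, 289 with the authors' values, 58 without a filter, 238 with probes well above background on all arrays, 60 with the slide as a block and 297 with a trended and robust prior, and 0 to 310 in leave-one-out. The cause was not tested.

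Basal against luminal cells kept its count within 1.5-fold under all settings in shLUC (5856 to 9596 in leave-one-out), and in shROR2 moved to 2828 with only the groups compared and to 3776 to 7559 in leave-one-out. Correlation of the luminal and basal effects (0.114) was 0.0811 without a filter, 0.184 with probes well above background on all arrays, 0.13 with the slide as a block and 0.0846 to 0.1203 in leave-one-out. With an estimated inter-gene correlation the lists passing fell to 4 of 12 in luminal cells, 5 of 12 in basal cells, 4 of 9 for the interaction and 6 of 11 for the average, counting 1 list not reported here. The cause was not tested.

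Called genes named in the text were followed here unless picked only through a list that did not pass in that comparison. None of those followed reversed. Over the alternatives other than leave-one-out, their calls held in 349 of 480 cases in basal cells, 324 of 396 in the average, 11 of 16 in luminal cells and all 1207 between compartments. In leave-one-out they held in 190 of 329, 119 of 288, 2 of 11 and all 847. Of the 284 basal calls, 244 were among the 253 with quantile normalization, 208 among the 541 with the authors' values and 128 among the 133 with the slide as a block.

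Values that reversed all lay near 0 or near background. The interaction of Wnt5a was 0.0086 with quantile normalization and 0.0089 with median scaling, that of Krt14 -0.0388 with normexp and -0.0381 with the authors' values, and that of Rock2 0.0186 and 0.0194 with these and 0.0148 with the mean of probes. Snai2 in the average, dim in luminal shLUC, was -0.0298 with normexp and -0.0278 with the authors' values, and Rock2 between compartments was -0.0508 and -0.0465. In luminal cells, Wnt4 was 0.0016 and Krt8 0.0015 with median scaling, Krt8 was 0.0066 with the slide as a block, Slc14a1 0.0166 with a floor, and Rock1 0.0576 with the mean of probes. Wnt5a between compartments was 0 with array weights. The Ror2 difference in basal cells was 0.27 with a floor. The cause was not tested.

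Leave-one-out reversed some genes that did not pass. In luminal cells the ranges were -0.0568 to 0.27 for Actn1, -0.58 to 0.70 for Axin2, -0.32 to 0.13 for Krt14, -0.0207 to 0.0140 for Krt8, -0.16 to 0.12 for Shroom2 and -0.20 to 0.18 for Wnt4. For the interaction they were -0.21 to 0.25 for Krt14, -0.18 to 0.0214 for Krt8, -0.43 to 0.0120 for Wnt4 and -0.14 to 0.0588 for Wnt5a. They were -0.18 to 0.0131 for Krt8 in basal cells, -0.20 to 0.0272 for Krt14 and -0.096 to 0.0024 for Krt8 in the average and -0.0574 to 0.0305 for Wnt5a between compartments. The Ror2 difference ranged from -1.19 to 0.0489 in basal cells. The cause was not tested.

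With a replicate block the calls were 0 in luminal cells, 37 in basal cells and 0 in the average, of which 36 of the 37 were also called without it. Wnt4 in luminal cells then stood at 0.0468 and Axin2 at -0.17. Lists then not called were general luminal markers in the average (0.101) and in basal cells (0.0594) and adipocyte transcripts in basal cells (0.0523), and lists called only then were the interferon (0.046) and endothelial lists (0.046) for the interaction. Arrays with the same number correlated after group means were removed at -0.037 to 0.040 (median 0.021, 15 pairs) and others at -0.068 to 0.052 (median -0.0085, 30 pairs), so the numbers gave no hint of pairing. The block spends degrees of freedom, which lowers counts by itself.

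Signal over background limited which probes were tested: Ror2 and Axin2 lay near background, and 53 of the basal calls had a dim group.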

Other observations

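All tests in this part were written before the results were seen. Each count of called genes was set beside counts from other splits of the same arrays. For basal shROR2 against shLUC, only 1 of 10 splits, the real one, reached 284, and the highest other count was 7. For basal against luminal shLUC cells, 1 of 10 splits reached 7939 and the highest other count was 0. Every other split there mixed basal with luminal arrays within a group, so low counts were fixed in advance and say nothing about chance. In both comparisons 10 splits are too few for a share under 0.05. For the average effect, 1 of 100 splits drawn from 200 within compartments, the real one, reached 135, and the highest other count was 5. These splits regrouped luminal and basal arrays separately. If both came from the same outgrowths, which the labels do not say, fewer splits would be possible and 1 of 100 would overstate the result.

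The probe for Trp63, a marker of the basal layer, showed no difference between compartments (0.15 between basal and luminal shLUC cells), unlike Krt5, Krt14 and Acta2. Of the values in the authors' table, 93.3% were whole multiples of 1/24, against 6.996% of multiples of 1/22, with a tolerance of 0.001. The 3 basal shROR2 arrays had weights of 0.571, 0.261 and 0.478 in an array weight fit, and every other array had 1.14 to 1.54.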
